A study of Gallus gallus with 20 samples.

How the data were processed

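The analysis rests on a single transcript table of adult chicken kidney, made from total RNA. Per the labels' protocols, the RNA was extracted with a kit that retains small RNA, and the RNA-seq library was made by a TruSeq protocol. The other 19 samples, all small RNA libraries, were not analysed here. Samples were grouped by their titles.

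Transcript abundance was estimated with Salmon on the galGal6 build, per the submitters' processing notes. The version, the library type setting and the making of the transcript set are not given in the sources used here. The deposited TPM values are scaled over all rows of the table together and sum to 1000000. The deposited estimated counts, which the authors' table gives beside TPM, are reads that Salmon split among rows sharing sequence. They were not whole in 27.7% of rows and summed to 21832272. The table also gives annotated and effective lengths, per the file headers. The effective length was 198.6 bases shorter than the annotated length for long rows, with exceptions. A TDRD12 transcript of 5806 bases had an effective length of 5594.4 bases.

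The rows comprised 43169 transcripts of 19650 named genes, 34512 transcripts with assembly identifiers and no gene name, 1350 numbered clusters, 258 repeat consensus sequences and 281 tRNA rows. Gene rows held 64.5% of reads, assembled transcripts 25.9%, clusters 9.49% and repeats 0.125%. A gene's reads can therefore be divided between its named row and an unnamed assembled transcript of the same place, which would lower the level of the named gene. How far this happened could not be measured without coordinates. Repeat classes were assigned from the consensus names.

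Gene levels were the sum of TPM over the transcripts that carry the gene's symbol in the row name. Listed symbols without a row of that name were matched through RefSeq transcripts of the GRCg7b gene table, which was used for names and gene types only, since its build differs from that of the table. Of the genes with a row, 15873 (80.8%) were found in that table. In the other direction, 11478 of its 14357 named protein-coding genes (79.9%) had a row, and all others were not analysed here.

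Before the data were examined, 23 gene lists, the processing alternatives and the rule for naming genes were fixed. The rule named every piRNA factor and AGO gene with a row, the 4 members with the highest TPM of each other list, its members at 0 where these were at most 3, the 20 genes with the highest TPM, and every listed W gene with a row. Some genes that the rule names are not reported here. Genes named outside this rule were chosen after their values were seen, and the text says so. Of the lists, 22 had at least 1 row. The list of PIWI genes had none, so the planned ratio of PIWIL2 to PIWIL1 and that of PIWI to AGO genes were not computed. AGO3, AGO4, DICER1, DDX4 and DAZL were likewise not analysed here. The ratios of AGO genes to GTSF1, of microRNA and germ cell medians to the piRNA median, and between nephron medians were not planned. The planned comparison of the Z and W chromosomes was left out because the gene table is of another build, and explanations planned for reads of PIWI genes were not tested.

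A gene was called detected at 1 TPM or more with at least 3 reads. Exact Poisson 95% intervals of the reads, rounded to whole numbers, were scaled to TPM, and a gene without reads was given the TPM of 3 reads as its limit. Shares have exact Clopper-Pearson intervals, ratios of genes have exact conditional binomial intervals, and medians of lists with at least 6 genes have order-statistic intervals. The intervals of genes, ratios and shares of reads cover counting error only. Reads without molecular identifiers are not independent molecules, and the splitting of shared reads adds error that these intervals leave out. Intervals of list medians and of shares detected treat the genes or clusters as a sample, which are not replicates. They do not include counting error. Each list median was placed among the medians of 10000 random lists of the same size, with a fixed seed, as a description of this library. With 1 library no p-value was computed.

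The random-list step was tested on simulated lists of 11 genes drawn from the 19650 genes. Lists drawn from all genes had a median percentile of 51.2, lists drawn from the highest-ranked genes 100, and lists drawn from the lower part of the ranking 2.98, over 200 lists each. The order-statistic interval held the true median in at least 98.5% of them.

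The alternatives were the most abundant transcript alone, annotated in place of effective length, removal of the 10 most abundant genes, other random-list backgrounds, lists matched on 10 classes of transcript length, and other detection thresholds. Removing rows shorter than 300 bases, the share of TPM for repeats, annotated length and the reads of the same genes for the share of top genes, and removing the leading pair of clusters were chosen after seeing the data. A percentile or count of detected genes was called moved when it changed by more than 1.5 times, a percentile also when it left the range set by the interval of its median. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.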

Results

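The series profiled chicken (Gallus gallus) kidney and testis RNA in 20 samples, and its title concerns piRNAs of the kidney, a somatic organ. The labels describe 19 small RNA libraries in 11 groups. Of these, 12 came from male and female kidney, with and without periodate oxidation, in 3 replicates per group. Oxidation depletes small RNAs that lack the terminal methyl group carried by piRNAs. A further 6 were made from immunoprecipitations of the PIWI proteins CILI and CIWI, 4 from testis and 2 from kidney. The last came from unoxidized testis of 12 weeks of age. The small RNA libraries were not analysed here. All values below come from 1 RNA-seq library of adult kidney, for which the labels give no sex. It held 21832272 estimated reads over 79570 rows. There are no replicates, so no difference was tested between samples. A named gene with few or no reads may have others on an unnamed assembled transcript, so its level can be too low. Intervals are 95% intervals. Those of single genes, repeats, ratios and shares of reads cover counting error only. Those of list medians and of shares detected treat the genes or clusters as a sample and do not include counting error.

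The measured piRNA factors, 11 of 24 fixed in advance, stood at low levels in this kidney. The measured microRNA pathway genes, 6 of 15, stood at higher ones. Core genes of both pathways, among them PIWIL1, PIWIL2, DDX4 and DICER1, were not measured. GTSF1, a cofactor of PIWI-guided silencing, had the highest level among the measured piRNA factors, at 2.80 TPM (47 reads, interval 2.05 to 3.72). TDRD1, a scaffold protein of germline granules, followed at 1.32 TPM (1.06 to 1.64), and ASZ1, a mitochondrial-surface factor of piRNA biogenesis, at 1.06 TPM (0.787 to 1.39). AGO1 and AGO2, the Argonautes of the microRNA pathway that were measured, stood at 16.0 TPM (15.2 to 16.8) and 10.9 TPM (9.89 to 12.0). AGO1 was 5.71-fold (4.27 to 7.80) and AGO2 3.90-fold (2.88 to 5.40) above GTSF1. These ratios were not planned, and they do not stand in for the planned ratio of PIWI to AGO genes.

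Among the 11 piRNA factors measured, 3 reached 1 TPM with at least 3 reads, a share of 27.3% (exact binomial interval 6.02 to 61.0). These were 1 of the 4 biogenesis factors and 2 of the 7 amplification and silencing factors. MAEL, a piRNA factor of the germline nuage, stood just under the threshold at 0.934 TPM (0.796 to 1.09), and the intervals of both MAEL and ASZ1 included 1 TPM. Of MAEL, the transcripts of 11113 and 11856 bases held 82.4% and 14.8% of TPM. Its transcripts of 3304 and 2928 bases had 1.28 and 0 reads. GPAT2 stood at 0.572 TPM, and the piRNA methyltransferase HENMT1 at 0.402 TPM from 12 reads. The piRNA trimmer PNLDC1 stood at 0.242 TPM from 9 reads, FKBP6 at 0.159 TPM from 7 reads and TDRD12 at 0.126 TPM. A TDRD12 transcript of 7202 bases with a non-coding identifier held 77.2% of that gene's TPM. No reads were assigned to TDRD6 or RNF17, for which 3 reads would have been 0.0300 and 0.0315 TPM. The median over the 11 factors was 0.402 TPM (order-statistic interval 0 to 1.32), and the medians of the biogenesis and of the amplification and silencing lists were 0.487 and 0.159 TPM. PIWIL2 and PIWIL1, the genes of CILI and CIWI, were not analysed here, nor were 13 of the 24 piRNA factors fixed in advance. Against 10000 random lists of 11 genes, the piRNA median lay at percentile 29.0 when all genes were drawn from, and at 3.24 when only genes with a symbol were. It lay at 15.0 with lists matched on transcript length, and at 1.47 among genes with at least 3 reads.

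All 6 measured members of the microRNA pathway were detected, with a median of 9.40 TPM (4.44 to 19.2), 23.3 times the piRNA median. The other 9 of the 15 members fixed in advance were not analysed here. The ratio was not planned and has no interval, and the interval of the piRNA median reached 0. The nuclear export receptor XPO5 had 19.2 TPM, and the Dicer partner TARBP2 had 7.87 TPM. The chaperone HSP90AB1, a gene singled out after its value was seen, stood at 4.44 TPM (3.80 to 5.15). Of AGO1, the transcript of 6506 bases held 86.7% of the gene's TPM and the transcript of 6547 bases 13.3%. AGO2 had a single named row, of 2595 bases. Reads from any AGO2 transcript outside that row are not in its level or its ratio to GTSF1. The microRNA median lay at percentile 87.2 of random lists, and at 65.2 among genes with a symbol. Genes that silence repeats through chromatin were also measured: 12 of 14 were detected, with a median of 6.53 TPM (1.87 to 18.8) at percentile 90.3, or 52.5 among genes with a symbol. MORC3 stood at 31.6 TPM, the histone methyltransferase EHMT1 at 18.9 TPM, the chromatin remodeller ATRX at 18.8 TPM and the maintenance DNA methyltransferase DNMT1 at 17.5 TPM.

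Genes of meiosis and germ cells were measured at levels close to those of the piRNA factors. Of 17 with a row, 6 were detected (35.3%, interval 14.2 to 61.7), and the list median of 0.398 TPM (0.0519 to 1.39) was 0.989 times that of the piRNA factors. The other 15 of the 32 members fixed in advance, among them DAZL, DMC1 and STRA8, were not analysed here. SYCP3, a component of the synaptonemal complex, stood at 6.04 TPM (5.31 to 6.84), STAGL, matched to the meiotic cohesin gene STAG3, at 5.17 TPM, TEX11 at 2.20 TPM and HORMAD2 at 1.40 TPM. No reads were assigned to MEIOB, MEI4 or SPATA16. The germ cell median lay at percentile 24.2 of random lists, and at 1.07 among genes with a symbol. Somatic gonad markers had a median of 0 TPM at percentile 1.60, with 1 of 6 detected. That gene was the follicle-stimulating hormone receptor FSHR at 2.68 TPM. The Sertoli and granulosa cell hormone AMH stood at 0.529 TPM, and FOXL2 and CYP19A1 were among 4 members without reads. Adrenal markers, included because the gland lies against the kidney, had 2 of 7 detected and a median of 0.0621 TPM at percentile 13.7. The steroid hydroxylase CYP17A1 stood at 4.68 TPM and STAR at 1.34 TPM, while CYP11A1 had 2 reads and TH and MC2R none. Among genes with a symbol, the percentiles of the somatic gonad and adrenal medians were 0.145 and 1.52, and with lists matched on transcript length 0.770 and 6.38. Among genes with at least 3 reads they were 12.7 and 19.3, from 2 and 3 members, and without rows shorter than 300 bases, a setting chosen after seeing the data, 0.890 and 9.11.

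**Figure D1:**
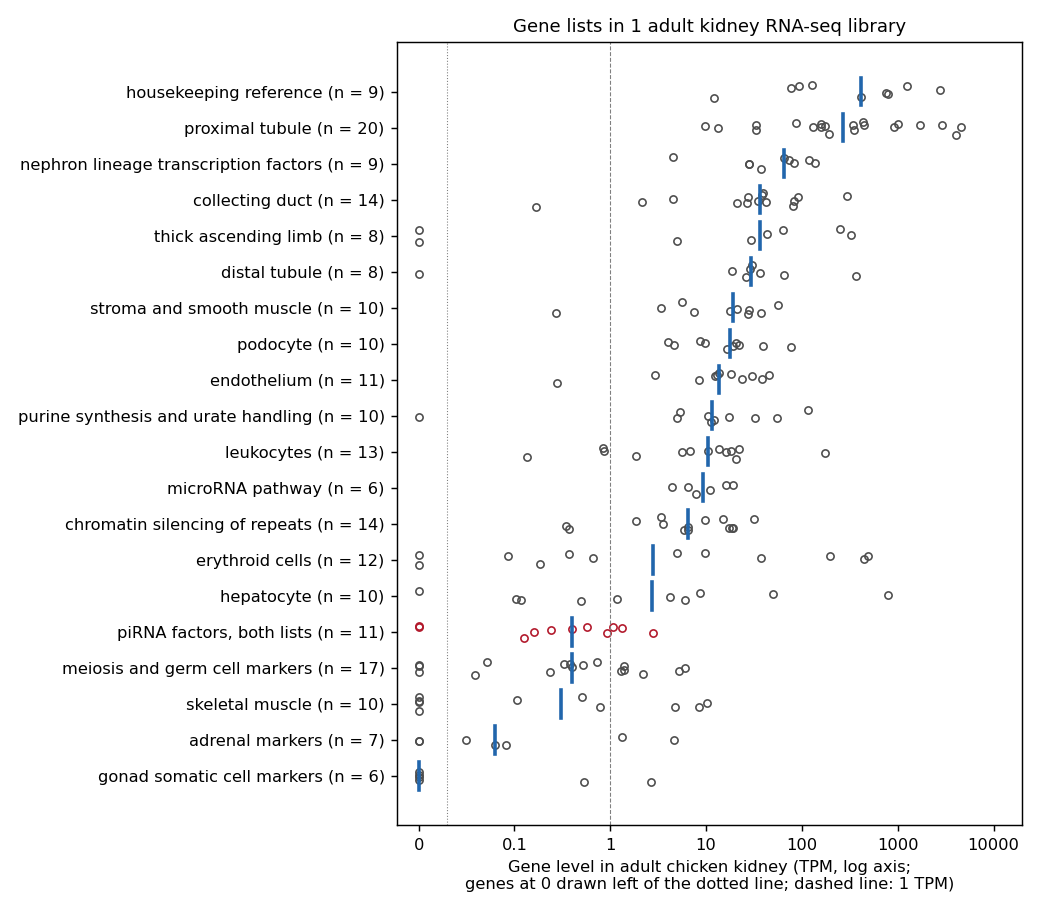
Gene levels in the adult kidney library, in TPM on a log axis, by gene list. Each circle is 1 gene, blue bars are list medians, red circles are the piRNA factors, and genes at 0 are drawn left of the dotted line. The measured piRNA factors lie at or below 2.80 TPM, and the proximal tubule list has a median of 267 TPM.

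Among the nephron lists, the highest median was that of the proximal tubule, the segment that reabsorbs most of the filtrate. All 20 measured proximal tubule genes, of 27 fixed in advance, were detected. Their median was 267 TPM (131 to 920), above all 10000 random lists. The phosphate transporter SLC34A1 reached 4055 TPM, the gluconeogenic enzyme PCK1 2908 TPM and the inositol oxygenase MIOX 1702 TPM. The proximal tubule median was 7.34 times that of the thick ascending limb, 9.05 times that of the distal tubule, 7.32 times that of the collecting duct and 15.1 times that of podocytes. Its interval overlapped those of the thick ascending limb and distal tubule medians, and lay above those of the collecting duct and podocytes.

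In the thick ascending limb list, 6 of 8 genes were detected, with a median of 36.4 TPM (0 to 329). CLDN10, a paracellular channel, stood at 329 TPM, the sodium-potassium-chloride cotransporter SLC12A1 at 250.5 TPM and KCNJ1 at 64.1 TPM. UMOD and EGF, made by this segment in mammals, had no reads on their named rows, where 3 reads would have been 0.173 and 0.0507 TPM. In the distal tubule list 7 of 8 genes were detected, with a median of 29.5 TPM (0 to 366). The calcium-binding protein CALB1 stood at 366 TPM, the thiazide-sensitive transporter SLC12A3 at 64.3 TPM, SLC8A1 at 36.9 TPM and TRPV6 at 30.3 TPM, while PVALB had no reads. In the collecting duct list 13 of 14 genes were detected, with a median of 36.6 TPM (4.49 to 82.2). The water channel AQP2 stood at 294 TPM, HSD11B2 at 90.2 TPM, the proton pump subunit ATP6V0D2 at 82.2 TPM and the sodium channel subunit SCNN1A at 79.8 TPM.

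All 10 measured podocyte genes were detected, with a median of 17.7 TPM. PODXL stood at 76.9 TPM, CD2AP at 21.9 TPM and TCF21 at 20.6 TPM. All 9 measured nephron lineage transcription factors were detected, with a median of 64.9 TPM (28.0 to 118). ESRRG stood at 135 TPM, PAX2 at 118 TPM and EMX2 at 73.0 TPM. Birds excrete nitrogen as urate, and 9 of 10 genes of purine synthesis and urate handling were detected, with a median of 11.7 TPM (5.02 to 55.2). XDH, which makes urate, stood at 114 TPM, ATIC at 55.2 TPM, ADA at 32.7 TPM and PAICS at 17.2 TPM. PNP had no reads on its named row, where 3 reads would have been 0.0745 TPM. These lists lay between percentiles 95.9 and 100 of random lists. Among genes with a symbol, the purine list lay at 80.9, podocytes at 94.6 and the transcription factors at 99.98.

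Endothelial, stromal and leukocyte markers were also measured. Of the endothelial genes 10 of 11 were detected, with a median of 13.5 TPM (2.95 to 38.8), and PLVAP stood at 45.2 TPM, PECAM1 at 38.8 TPM, VWF at 30.1 TPM and KDR at 23.6 TPM. Of the stromal and smooth muscle genes 9 of 10 were detected, with a median of 19.3 TPM (3.35 to 37.0), and ACTA2 stood at 56.4 TPM, COL1A2 at 37.0 TPM, TAGLN at 28.0 TPM and COL1A1 at 27.3 TPM. Of the leukocyte genes 10 of 13 were detected, with a median of 10.5 TPM (0.857 to 20.5). The invariant chain CD74 stood at 173 TPM, the T cell genes CD3D and CD3E at 21.8 and 18.1 TPM, and LCP1 at 20.5 TPM.

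Blood was represented by the globin genes HBA1 at 486 TPM, HBBA at 448 TPM and HBM at 197 TPM, and by the anion exchanger SLC4A1 at 37.2 TPM. Only 6 of the 12 erythroid genes were detected. HBBR and HBZ had no reads, and the list median of 2.79 TPM (0.0863 to 197) was 0.0104 times the proximal tubule median. This ratio does not measure the amount of blood in the sample, since HBA1, HBBA and HBM stood far above the list median. Of the hepatocyte genes 6 of 10 were detected, with a median of 2.71 TPM (0.104 to 50.4). APOB stood at 792 TPM, APOH at 50.4 TPM, FGA at 8.57 TPM and C3 at 5.96 TPM, and TTR had no reads. Skeletal muscle genes had 3 of 10 detected and a median of 0.306 TPM (0 to 8.49), with ACTA1 at 10.2 TPM, MYL1 at 8.49 TPM, ACTN2 at 4.71 TPM and TNNI2 at 0.791 TPM. The percentiles of the erythroid, hepatocyte and skeletal muscle medians were 66.5, 64.8 and 21.3. Among genes with a symbol they were 18.3, 20.3 and 2.00. Among genes with at least 3 reads they were 99.3, 38.9 and 41.6, but only 7, 8 and 5 list members passed that filter. With lists matched on transcript length they were 94.6, 59.5 and 34.5. All 9 measured housekeeping genes, of 15 fixed in advance, were detected, with a median of 411 TPM (77.1 to 1251). GAPDH stood at 2729 TPM, B2M at 1251 TPM, UBB at 797 TPM and RPS6 at 757 TPM.

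A few genes took much of the library's TPM. LOC112532220, a small nuclear RNA of 164 bases, held 15.3% of all TPM with 0.0738% of reads. AvBD10, an avian beta-defensin, held 5.29% of TPM and 1.75% of reads, and AVDL held 1.61% and 0.531%. The small nucleolar RNAs LOC112530237, LOC112530089, LOC112532460, LOC112532456 and LOC112530098 held 3.31%, 1.55%, 0.427%, 0.332% and 0.227% of TPM. FTH1, the ferritin heavy chain, reached 6612 TPM, MUC4L 3201 TPM, APOA1 3129 TPM and FXYD2, a subunit of the sodium pump, 2088 TPM. ACSM4L stood at 2014 TPM, ACTC2L at 2013 TPM and TPT1 at 1618 TPM.

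The 10 genes with the highest TPM held 29.4% of TPM, and the top 100 held 38.1%. The same genes held 3.89% and 13.5% of reads, and the 10 and the 100 genes with the most reads held 7.46% and 16.5% of reads. Rows shorter than 300 bases held 35.4% of TPM but 0.493% of reads. Of 19650 genes with a row, 10098 (51.4%) were detected, and none of the 13 mitochondrial protein-coding genes was analysed here.

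**Figure D2:**
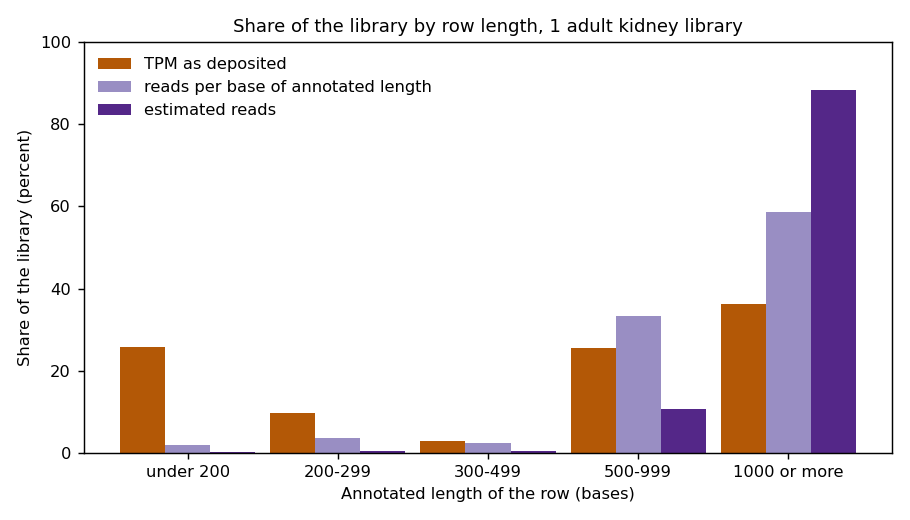
Share of the adult kidney library, in percent, held by rows of each annotated length in bases, as deposited TPM, as reads per base of annotated length and as estimated reads. Rows of 1000 bases or more held 36.2% of TPM and 88.5% of reads.

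Repeat consensus sequences drew 27328 reads, 0.125% of the library, and endogenous retroviruses led them. LTR retrotransposons held 63.3% (62.7 to 63.8) and LINE retrotransposons 35.7% (35.2 to 36.3) of the repeat reads. RSV_I, the internal part of a Rous sarcoma virus-related element, drew 10250.5 reads and stood at 95.6 TPM (93.7 to 97.4), above 96.8% of genes. A consensus row can gather reads from several copies of its family, so this level is not that of a single place in the genome. GGERV20_I, the next by reads, stood at 40.7 TPM, and RSV_I had 3.07 times (2.95 to 3.19) its reads. In TPM, which allows for length, the ratio was 2.35 (2.26 to 2.44). Among the LINE elements, led by the CR1 group, CR1-C drew 1854 reads and CR1-F2 1792 reads, at 27.0 and 111 TPM. CR1-F2, of 1217 bases, thus stood above RSV_I, of 6976 bases, in TPM. EAVHP_I, the internal part of an endogenous avian retrovirus, stood at 24.3 TPM. Internal parts held 89.6% of the LTR class reads, with 1515.6 reads on 50 LTR sequences. The 6 SINE and MIR rows and the 281 tRNA rows had no reads. The tRNA rows had a median length of 73 bases, under the 198.6 bases taken off long rows for effective length. Their lack of reads therefore does not show an absence of tRNA. Reads of repeats that lie inside genes or assembled transcripts can be shared with those rows.

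**Figure D3:**
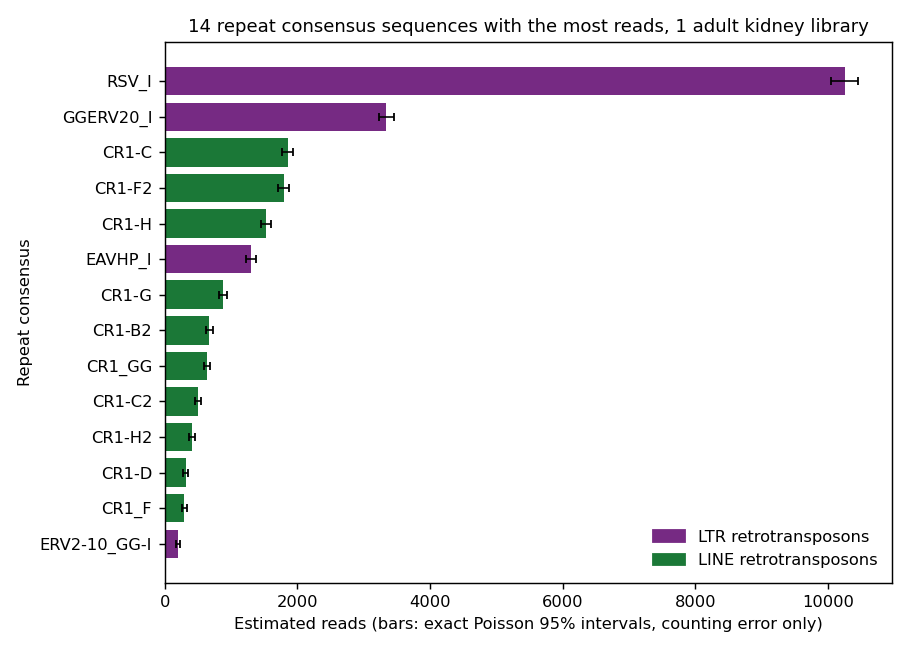
Estimated reads on the 14 repeat consensus sequences with the most reads in the adult kidney library, with exact Poisson 95% intervals that cover counting error only. Purple bars are LTR and green bars LINE retrotransposons, and RSV_I leads with 10250.5 reads.

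The table also listed 1350 numbered clusters, which the labels do not define. Cluster577, of 851 bases, and cluster175, of 15744 bases, drew 54.9% and 39.9% of the cluster reads and stood at 110255 and 3363 TPM. All clusters together held 9.49% of the library's reads, and without this pair, a setting chosen after seeing the data, the share was 0.488%. Of the remaining clusters, cluster585 drew 15259 reads and cluster669 7126 reads. Of the 1350 clusters, 182 (13.5%, 11.7 to 15.4) were detected and 655 had no reads. RNA-seq reads on a cluster count longer transcripts from that place and not piRNAs, and whether the clusters overlap genes or share reads with them was not determined.

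The W-linked genes HINTW and SPIN1W, carried in birds by females, had no reads, where 3 reads would have been 0.455 and 0.0440 TPM. Their Z-linked partners, looked up after these values were seen, stood at 401 TPM for HINT1Z (385 to 418) and 39.0 TPM for SPIN1Z (37.6 to 40.4).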

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

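All tests in this part were chosen after the results were seen. Assembled transcripts without a gene name, which stand outside every list and comparison, held 25.9% of the library's reads. They were singled out because this signal lies far above the 3 reads taken as the limit. The assembled transcript with the most reads, from locus 300990 and 3529 bases long, drew 276606 reads, 1.27% of the library. No explanation was tested for either value, since assembled transcripts were not tied to genes here.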

How the results depend on the processing

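Tests without rows shorter than 300 bases, without the leading pair of clusters, of annotated length and of the reads of the same genes for the top genes, and of TPM for repeats were chosen after the results were seen. No paired analysis was possible because the replicate numbers shared by the small RNA groups belong to libraries not analysed here, and the table comes from 1 library. Of 160 percentiles under 7 settings 128 were not called moved, nor were 145 of 161 counts of detected genes. This tally is a weak measure of stability, since high percentiles have little room for a fold rise and wide median intervals allow large changes. Among genes with at least 3 reads, erythroid went from 66.5 to 99.3 and leukocytes from 96.2 to 79.2 without being called moved. The combined piRNA list also repeats the members of its parts. The most abundant transcript alone and annotated length moved none of the list percentiles or detected counts. Depth limits the lowest genes, since PNLDC1, FKBP6 and CYP11A1 rest on fewer than 10 reads. The cause of the changes below was not tested, except that a stricter or looser threshold changes a count by construction.

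Among genes with a symbol, percentiles fell to 3.24 for the piRNA factors (7.44 for biogenesis, 3.33 for amplification and silencing), 1.07 for germ cell genes, 65.2 for the microRNA pathway and 52.5 for chromatin silencing. They were 0.145 for the somatic gonad, 1.52 for adrenal, 18.3 for erythroid, 20.3 for hepatocyte, 2.00 for skeletal muscle and 0.895 for W-linked genes. Among genes with at least 3 reads, which also dropped list members with fewer, they were 1.47 for the piRNA factors (2.89 and 9.73), 0.980 for germ cell genes, 65.0 for the microRNA pathway, 51.9 for chromatin silencing, 12.7 for the somatic gonad, 38.9 for hepatocyte and 41.6 for skeletal muscle genes. Those of the somatic gonad and skeletal muscle lay above their values of 1.60 and 21.3 among all genes, as did adrenal at 19.3 against 13.7 and erythroid at 99.3 against 66.5. The filter kept only 2, 5, 3 and 7 members of these lists, in that order. The erythroid percentile was 94.6 with lists matched on length.

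With random lists matched on transcript length, percentiles were 15.0 for the piRNA factors (14.6 and 12.6), 0.770 for the somatic gonad, 6.38 for adrenal, 34.5 for skeletal muscle and 1.44 for W-linked genes. Without rows shorter than 300 bases they were 0.890 for the somatic gonad, 9.11 for adrenal and 1.92 for W-linked genes, and without the 10 most abundant genes 2.87 for W-linked genes. The W-linked list held 2 measured genes, both without reads. Its percentile thus reflects only how often random lists also had a median of 0, and any change in it was called moved by construction.

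At 0.1 TPM, 9 piRNA factors (4 and 5 by list), 12 germ cell, 2 somatic gonad and 5 skeletal muscle genes were detected. At 10 reads with no TPM limit these counts were 7 piRNA factors (3 and 4) and 2 somatic gonad genes. At 5 TPM, 2 germ cell genes and 0 piRNA factors were detected, with 0 in each piRNA list, the somatic gonad and the adrenal list.

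The 10 and 100 genes with the highest TPM, at 29.4% and 38.1% of TPM, held 3.89% and 13.5% of reads. Ranked anew, the top 10 and 100 genes held 7.46% and 16.5% by reads, and 14.3% and 25.4% with annotated length. The cluster share of reads was 0.488% without the leading pair. Leaving out short rows raised every remaining TPM 1.55-fold, and leaving out the 10 most abundant genes raised piRNA factors 1.42-fold. Annotated length raised the 9 piRNA factors with reads 1.49- to 1.73-fold, and 4 of 11 were detected under each of these settings. LTR and LINE elements held 65.6% and 32.1% of repeat TPM.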

Other observations

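All tests in this part were chosen after the results were seen, as were the genes named here outside the lists. Gene families outside the lists were also looked up. All 12 glutathione S-transferase genes were detected, with a median of 127 TPM, and GSTM2 stood at 519 TPM, GSTA3 at 424 TPM and GSTK1 at 394 TPM. Of 44 cytochrome P450 genes 27 were detected and 6 had no reads, and the family median was 5.11 TPM. Its members included CYP4B7 at 1367 TPM, CYP2AC1 at 937 TPM and CYP24A1, which inactivates vitamin D, at 247 TPM. Catalase (CAT) stood at 1526 TPM, UGT1A1 at 1279.7 TPM and the alcohol dehydrogenase ADH1C at 1074 TPM. The sodium pump subunit ATP1B1 stood at 1328 TPM, the sulfate transporter SLC26A1 at 488 TPM and the organic cation transporter SLC22A2 at 134 TPM. All 37 ribosomal protein genes were detected, with a median of 397 TPM and RPS25 highest at 1280.1 TPM.

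Beta-defensin expression in this kidney was almost entirely AvBD10. It stood at 52859 TPM, while AvBD9 stood at 12.3 TPM, AvBD11 at 4.60 TPM and AvBD12 at 1.03 TPM from 5 reads, and 9 of 14 family members had no reads. AVDL stood at 16101 TPM, against 0.490 TPM from 3 reads for avidin (AVD). Lysozyme (LYZ), another egg-white protein, had 2 reads. Among toll-like receptors 5 of 10 were detected, with a median of 1.22 TPM, led by TLR3 at 14.6 TPM. Of 40 HOX genes 25 were detected, with a median of 6.58 TPM, led by HOXB6 at 123 TPM, HOXD8 at 57.7 TPM, HOXB4 at 37.7 TPM and HOXB9 at 35.9 TPM. TDRD3, a Tudor protein outside the piRNA lists, stood at 19.6 TPM (18.2 to 21.1).

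Genes shorter than 300 bases led the TPM values, with 6 among the top 20. A candidate explanation is division by a small effective length. With annotated length, rows shorter than 300 bases held 5.59% of the scaled total against 35.4% of TPM. The direction of that change is set by the calculation and its size is not. Abundant small nuclear and nucleolar RNA stays open, since 3 of the 6 genes remained in the top 20 with annotated length, LOC112532220 at rank 3.

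The piRNA factor reads in this kidney could come from germ cells of an adjacent gonad, a hypothesis set against piRNA factors of the kidney itself. Of the measured germ cell markers 35.3% were detected, against 27.3% of the measured piRNA factors, and the intervals overlap widely. Of the 32 germ cell markers fixed in advance, 15 were not analysed here, DAZL among them. The germ cell markers were led by SYCP3 at 6.04 TPM, while FSHR was the sole somatic gonad marker detected. These values do not separate germ cells from low expression in kidney cells, and no gonad library was compared.

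Almost no reads lay on W copies of W and Z gene pairs. Over HINTW, SPIN1W and ATP5A1W and their Z partners, the W copies held 0.0327% (0.0131 to 0.0674) of the reads, all 7 of them on ATP5A1W, against 594 TPM for ATP5A1Z. This is what a male bird may show, as a hypothesis. The open point is GLYATL3W, named as a W gene but without an entry in the gene table used, which held 24.9% (21.0 to 29.2) of the reads of GLYATL3 and GLYATL3W. W reads assigned to similar Z rows also stay open, because no sequences were compared.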
